A study of Homo sapiens with 4 samples.

How the data were processed

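Hep3B cells, an established human hepatocellular carcinoma line, carried a doxycycline-inducible fusion of the cytidine deaminase APOBEC1 to either EGFP or PUS1. In this approach, called STAMP, the deaminase converts C to U near the places where its partner binds RNA, and RNA sequencing reads the conversions as C-to-T mismatches. Total RNA was sequenced from 4 libraries, 1 per group: the EGFP line and the PUS1 line, each without doxycycline and with doxycycline at 1 µg/mL. There were no replicates, so no test across conditions was possible. Every interval and p-value below treats reads, sites or genes of 1 library as independent and measures no spread between libraries.

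Per the submitters' processing notes, cutadapt 1.16, Bowtie2 2.3.3.1 and BWA were used with build hg19, with no role or order stated. The editing caller, its thresholds and the treatment of duplicate reads are not given in the sources used here. Per the series' design text, the authors kept sites that appeared in the cells with the induced PUS1 fusion alone, and they intersected host genes with genes already known to be pseudouridylated. Whether the table used here is from before or after that intersection is not stated. The deposited table gives, per site, a read count for each library, a ratio for the 3 other libraries, and a general editing ratio. The deposited read count of the library with the induced PUS1 fusion was found to be coverage: multiplied by the deposited editing ratio, a fraction between 0 and 1, it gave a whole number at 4461 of 4461 sites within a tolerance of 1e-05. The product was taken as the number of edited reads. The editing ratio column names no library, and its levels are the authors' values. In the other 3 libraries every deposited count and every deposited fraction was 0. A 0 there can mean that no site was called, not that reads covered the site without an edit. The selection of sites requires the fractions of 0 but not the counts of 0, whose cause was not tested. The planned comparisons between libraries and the planned Fisher tests per site were therefore not run. Total reads per library were not used here, so the depth is known only at the listed sites.

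Shares of sites and levels of single sites carry exact Clopper-Pearson 95% intervals. These treat reads as independent molecules and sites as independent, neither of which is known. Those of single-site levels also make no allowance for the listing of edited sites only, so a lower bound is not a minimum level. Region labels (3' UTR, exonic, 5' UTR) and positions are those of the deposited table on hg19; whether its positions count from 0 or from 1 is not stated, and strand and bases were not used here. Gene names were matched to a GRCh38.p14 gene table for names only: 1813 of 1839 matched as current symbols, 25 as synonyms and 1 not at all. No genome sequence was used, so the base context of the sites, the HRUAR motif, random placement of sites and lists matched on exon length were not analysed here.

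Before the data were examined, 20 gene lists and the rule for named genes were fixed. Named are the 10 genes with the most sites, the 10 sites with the highest level at a coverage of 20 or more, up to 4 members of each list by number of sites, every pseudouridine synthase with a site, APOB, MYC and IRS1 whether listed or not, and the 3 sites with the highest coverage. Some items that this rule names are not reported here. Only counts of list members had been planned for the case without a suitable reference. A two-sided Fisher's exact test of each list against the members of the other lists, with Benjamini-Hochberg adjustment over the 20 lists, was added after the memberships had been seen. Also chosen after the table was seen were the comparison of regions by number of edited reads, the fit of a conversion rate, the ratio of pair densities and the test of gene symbol families. The conversion rate was fitted by maximum likelihood with a zero-truncated binomial model to sites with a coverage of at most 20, where 1 edited read reaches the lowest listed level of 5%. The comparison of regions used a two-sided Fisher's exact test, a permutation test within each coverage (100000 permutations) and resampling by gene (10000 resamples). The pair ratio used 10000 resamples by gene.

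Alternatives were minimum coverages of 10, 20, 30 and 50 reads, minimum levels of 5, 10 and 20%, 1 row per position, other windows, a gene left out and a minimum of 2 sites per gene. A minimum of 2 edited reads, 1 random site per gene (the median of 200 draws) and other lists without ribosomal proteins were added after the data were seen. The statistics were tested on simulated data: a rate of 0.2% was recovered as 0.202% over 46871 simulated sites, a rate of 5% as 5.06% over 8880 simulated sites, and 1 of 1 raised list was called among 627 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.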

Results

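To find the mRNAs bound by PUS1, a pseudouridine synthase, C-to-U editing by the PUS1-APOBEC1 fusion was mapped in Hep3B hepatocellular carcinoma cells. The EGFP-APOBEC1 fusion and both lines without doxycycline served as controls, with 1 library per group and no replicates. The table holds 4461 edited positions in 1839 genes on 23 chromosomes, all from the library with the induced PUS1 fusion. In the other 3 libraries every site is listed at 0, in reads and in editing fraction. The selection of sites requires the fractions of 0 but not the read counts of 0, whose cause was not tested. The table therefore gives no measured background. Chromosome 1 held 473 sites (10.6%) and chromosome 21 held 43.

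Most listed sites rested on a single edited read. Exactly 1 edited read was found at 4368 sites (97.9%), 2 at 82, 3 at 8, 4 at 2 and 5 at 1. Coverage ran from 5 to 63 reads with a median of 12 (quartiles 8 and 16), and 46 sites were covered by more than 20 reads. The editing level ran from 5% to 60% with a median of 9.09% (quartiles 6.25% and 12.5%), and 4569 of 53996 reads over all sites were edited (8.46%). A level made of 1 edited read is set by the coverage alone. The exact 95% interval was 0.505% to 71.6% for 1 of 5 reads, 0.211% to 38.5% for 1 of 12 and 0.127% to 24.9% for 1 of 20. Because only edited sites are listed, the lower bounds are too high to be read as minimum levels. Levels of most single sites were thus not distinguishable from one another at this depth.

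**Figure D1:**
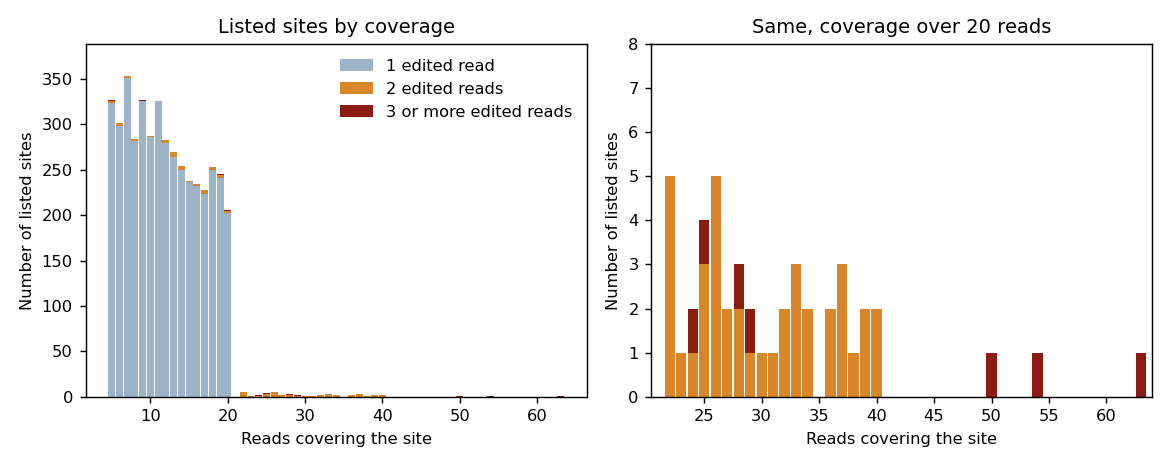
Number of listed sites (y axis) by the number of reads covering the site (x axis) in the library with the induced PUS1 fusion, stacked by the number of edited reads; the right panel repeats the sites with a coverage over 20. Sites with 1 edited read end at a coverage of 20, and the 46 sites beyond it all have 2 or more edited reads.

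The 10 sites with the highest levels among the 252 with a coverage of 20 or more all lay in 3' UTRs. Of all 252, 60.7% were in 3' UTRs. Of the 46 with a coverage over 20, which all had 2 or more edited reads, 41 were (89.1%). ASPH, an aspartyl hydroxylase of the endoplasmic reticulum, held 2 of these 10 sites: 20% at position 62537987 of chromosome 8 (4 of 20 reads, 5.73% to 43.7%) and 12% at position 62538409 (3 of 25 reads, 2.55% to 31.2%). EIF4EBP2, a repressor of cap-dependent translation, reached 12.5% at position 72182208 of chromosome 10 (3 of 24 reads, 2.66% to 32.4%). ATP13A3, a P-type ATPase, reached 10.7% at position 194124413 of chromosome 3 with 3 of 28 reads, and KCTD20 reached 10.3% at position 36457823 of chromosome 6 with 3 of 29 reads. LAMC1, a laminin chain, had the most edited reads of any site: 10% at position 183113914 of chromosome 1 (5 of 50 reads, 3.33% to 21.8%). The actin nucleation subunit ACTR3 and the dynein light intermediate chain DYNC1LI2 each had 2 of 20 edited reads (10%, 1.23% to 31.7%), and the kinase MAPKAPK2 had 2 of 22 (9.09%). MAPKAPK2 was 1 of 5 sites with that level and coverage, and it took the last place by position alone. The deepest sites were in EIF2S3, a subunit of a translation initiation factor, with 4 of 63 reads at position 24095492 of chromosome X (6.35%, 1.76% to 15.5%), and in SREBF2, a transcription factor of sterol synthesis, with 3 of 54 reads at position 42301990 of chromosome 22 (5.56%, interval up to 15.4%). The intervals of all these sites overlapped.

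Sites were spread over many genes. A single site was found in 778 genes, 2 in 450 and 3 in 259, and 21 genes had 10 or more, together 252 sites. CBX5, a heterochromatin protein, had the most with 17 sites, of which 16 were in the 3' UTR. It was followed by the lysosomal membrane protein LAMP2 with 16, and by the cargo receptor TMED5, the scaffold AHNAK and carboxypeptidase D (CPD) with 15 each. The lysine methyltransferase SETD7 had 14, the cadherin FAT1 13, the acyltransferase LPGAT1 and the Argonaute protein AGO2 12 each, and the aminotransferase BCAT1 11. BCAT1 was not the only gene with 11 sites, and it took the last place by its highest level or by name. The region differed among these genes: all 15 sites of CPD and all 11 of BCAT1 were in the 3' UTR, while 14 of 15 in AHNAK and all 13 in FAT1 were exonic. Lengths of regions were not used, so neither the counts nor the regions are adjusted for the positions that each gene offers. No site of CBX5, LAMP2, AHNAK, SETD7, FAT1, AGO2 or BCAT1 had more than 1 edited read, while TMED5 and CPD each had 2 sites with 2 or more. Across all genes, 846 sites (19%) had another site of the same gene within 100 bases.

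**Figure D2:**
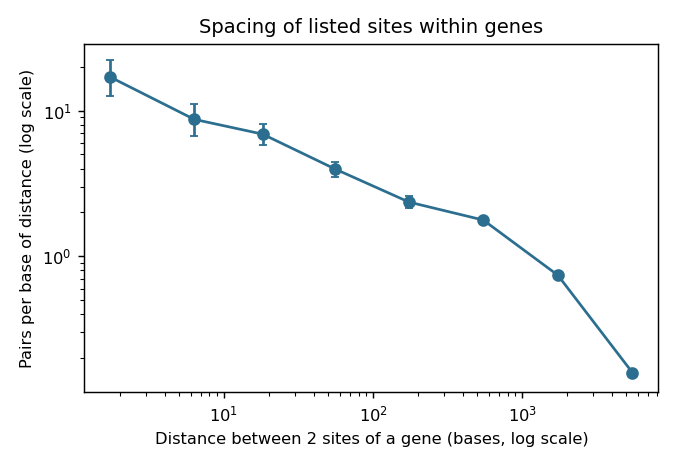
Pairs of sites in the same gene per base of distance (y axis, log scale) against their distance in bases (x axis, log scale), in bins from 1 to 10000 bases; lines on the points are 95% Poisson intervals, which treat pairs as independent. Density falls with distance, from 17 pairs per base at 1 to 3 bases to 0.159 at 3001 to 10000.

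**Figure D3:**
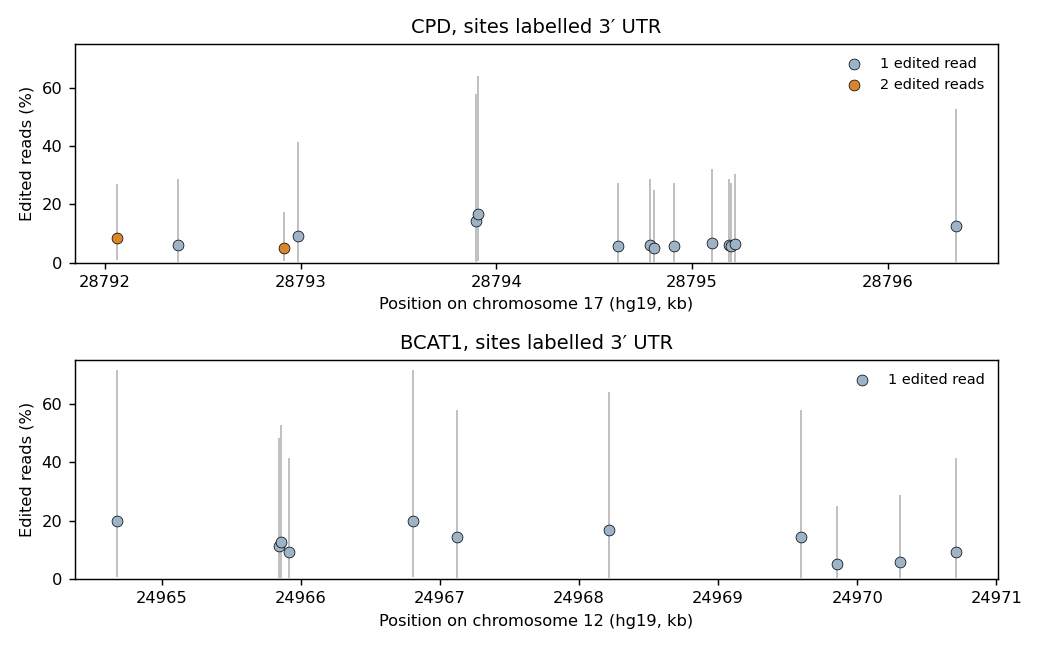
Share of edited reads in percent (y axis) against the hg19 position in kb (x axis) for the sites of CPD and BCAT1; points are single sites colored by edited reads and gray lines are exact 95% intervals. The 15 sites of CPD and the 11 of BCAT1 overlap in their intervals.

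The 3' UTR held the largest share of the sites, as labelled in the table. These were 2514 sites (56.4%, 54.9% to 57.8%) in 1159 genes, against 1731 exonic sites (38.8%) in 1065 genes and 216 in 5' UTRs (4.84%) in 194 genes. Among sites with 2 or more edited reads, 75 of 93 were in the 3' UTR (80.6%). Coverage sets how many edited reads a listed site must have, so the comparison was made at a coverage of at most 20. There, 34 of 47 sites with 2 or more edited reads were in the 3' UTR (72.3%), against 2439 of 4368 with 1 (55.8%), an odds ratio of 2.07 (1.06 to 4.28, two-sided Fisher's exact p = 0.0262). This test was chosen after the table was seen. The odds ratio depended on coverage: it was 3.95 at a coverage of at least 10 (exact p = 0.00090), so sites with fewer reads lowered it. No separate value was computed for the sites with fewer reads. With 1 random site per gene, drawn from sites of all coverages, the odds ratio was 1.95 (median exact p = 0.287). Drawn only from sites with a coverage of at most 20, it was 1.85 (median exact p = 0.300). The odds ratio was 0.775 at a level of at least 20% (exact p = 0.785), a filter that selects on edited reads and left 14 sites with 2 or more.

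**Figure D4:**
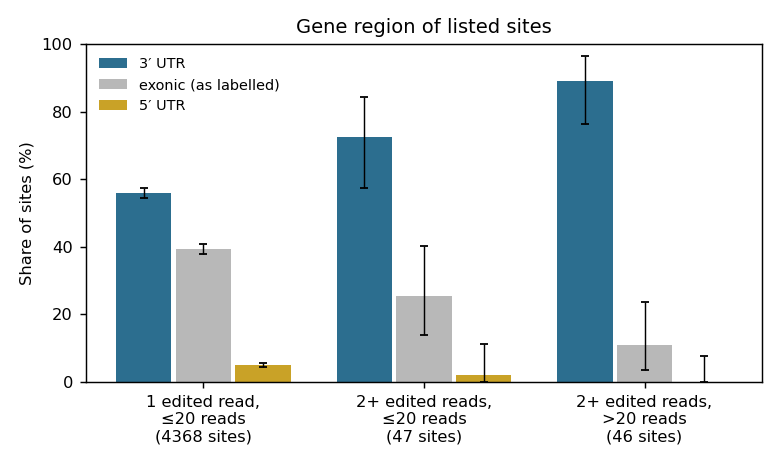
Share of sites in percent (y axis) in each gene region, for sites with 1 edited read and with 2 or more, at a coverage of at most 20 or above it (x axis); bars are shares and lines are exact 95% intervals. The 3' UTR share is 55.8% for 1 edited read and 72.3% for 2 or more at a coverage of at most 20.

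Genes of nuclear transport carried sites more often than the other listed genes. Of 26 members, 17 had a site (odds ratio 7.70, Fisher's exact adjusted p = 2.15e-05), among them the importin IPO5 with 7 sites, the importin alpha KPNA6 and transportin TNPO1 with 6 each, and the nucleoporin NUP210 with 5. Oncogenes and growth signalling genes of liver cancer followed with 19 of 38 (odds ratio 4.06, Fisher's exact adjusted p = 0.000603). The receptor MET had 9 sites, the insulin receptor substrate IRS2 had 6, and IGF2 and NRAS had 4 each. Over all 19 lists of liver-cell and housekeeping functions, 132 of 610 members had a site (21.6%). The test was added after memberships were seen, and it has no background of expressed genes. A gene must be expressed to carry a site, and a long transcript offers more positions. High coverage can work the other way, since no site with 1 edited read is listed above a coverage of 20. Highly expressed genes can therefore show fewer sites, and this was not tested. Neither list passed the test with at least 2 edited reads per site, where 11 list members were left (odds ratios 2.3 and 3.48), or at a coverage of at least 30 or 50, where 4 and 2 were left. Nuclear transport also did not at a coverage of at least 20 (odds ratio 2.03), where oncogenes did (odds ratio 6.95). Oncogenes did not at a level of at least 20% (odds ratio 3.18), where nuclear transport did (odds ratio 14.3). With ribosomal proteins taken out of the other lists, both passed (odds ratios 7.04 for nuclear transport and 3.70 for oncogenes).

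No other list passed the test on the table as deposited. Cytosolic ribosomal proteins had a site in 8 of 78 members (odds ratio 0.376, Fisher's exact adjusted p = 0.0516). This list passed the test at a coverage of at least 10 (odds ratio 0.335, exact adjusted p = 0.0495) and with at least 2 sites per gene (odds ratio 0.156, exact adjusted p = 0.0175). The end of sites with 1 edited read at a coverage of 20 applies to ribosomal protein genes too, and its effect was not tested. There were 5 sites in RPL37, 2 in RPL4 and 1 each in RPL27A and RPL3. Of the translation factors 12 of 48 had a site, led by EIF4EBP2 with 7, EIF4G1 with 6, EIF2S3 with 4 and EIF4G3 with 3. Splicing factors had 12 of 37, with 7 sites in HNRNPC, 6 in HNRNPA3, 4 in HNRNPDL and 2 in SRSF1. Endoplasmic reticulum stress and folding had 8 of 26, with 9 sites in the degradation factor SEL1L and 3 each in ATF6 and SYVN1. Chromatin genes and histones had 7 of 23, with 10 sites in the methyltransferase KMT2D and 8 each in CHD4 and H2AFV. Ribosomal protein genes, HNRNPA3, H2AFV and CYCS have near-identical pseudogene copies, and their sites are uncertain. Mapping to such copies was not examined for any gene, so sites of other genes may share this limit.

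Hepatocyte secreted proteins had 4 of 32, with 5 sites in the kininogen KNG1, 3 in the coagulation factor F5, 2 in ALB and 1 in FGG. Cholesterol and lipid synthesis had 6 of 28, with 4 sites in SREBF2, 3 in ACLY and 2 in ACACA. Glycolysis had 4 of 20, with 2 sites each in SLC2A1, HK2 and PFKFB3, and oxidative phosphorylation had 4 of 37, with 3 in CYCS and 2 in SDHD. Cell cycle genes had 7 of 41, with 3 sites in CCND3 and 2 in CDK2, and tumour suppressors had 3 of 17, with 3 sites each in APC and BAP1. The proteasome had 3 of 34, with 2 sites each in PSMD13 and PSMB2. Aminoacyl-tRNA synthetases had 3 of 26, with 3 exonic sites each in VARS and WARS. Heat shock proteins had 3 of 23, with 8 sites in HSPA4, and the cytoskeleton had 5 of 34, with 8 sites in the membrane linker MSN, all in the 3' UTR. RNA modification enzymes other than pseudouridine synthases had 5 of 31, with 5 sites in IGF2BP1 and 4 in YTHDF3. None of 17 markers of fibroblasts, leukocytes and endothelium had a site (Fisher's exact adjusted p = 0.153).

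**Figure D5:**
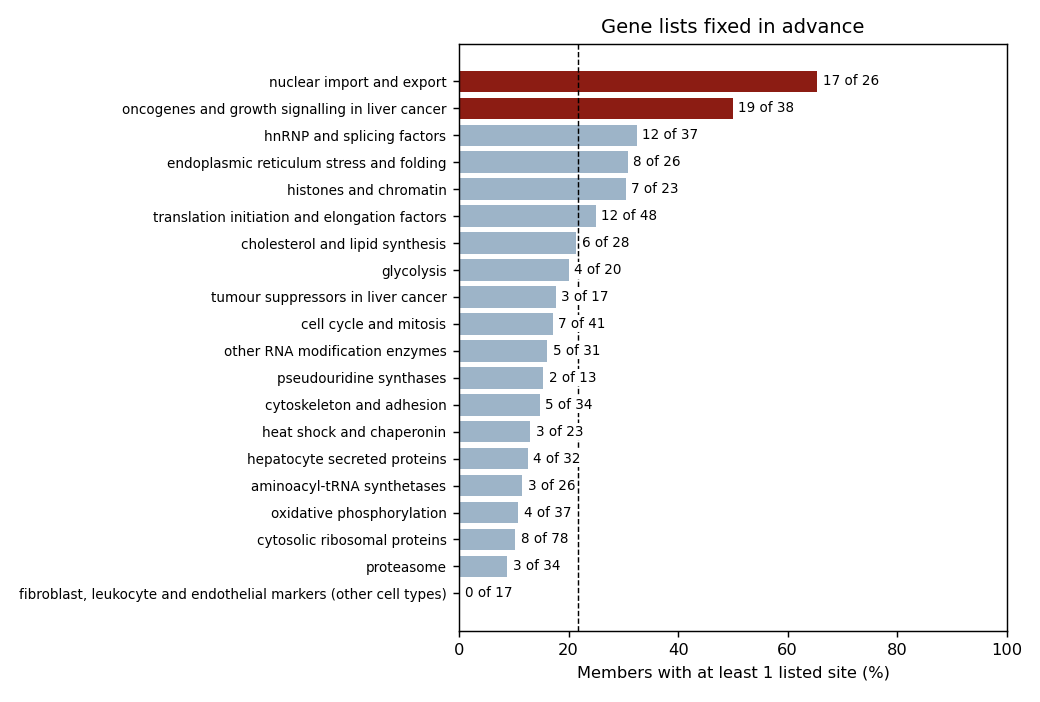
Share of the members of each of the 20 gene lists with at least 1 listed site, in percent (x axis), with the numbers beside each bar; red bars passed the Fisher's exact test after adjustment and the dashed line is the 21.6% of all members of the 19 lists other than the markers of other cell types. Nuclear transport (17 of 26) and liver cancer oncogenes (19 of 38) are the red bars.

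Among 13 pseudouridine synthases 2 had a site. DKC1, the synthase of box H/ACA ribonucleoproteins, had 3 exonic sites with 1 edited read each, out of 18, 10 and 8 reads, and RPUSD1 had 1 site in the 3' UTR with 1 of 13 reads. PUS1 itself and APOB, whose mRNA is the natural substrate of APOBEC1, had no site in the table analysed here. Sites edited in a control library were left out by selection, and no site with 1 edited read is listed above a coverage of 20. The absence of these genes therefore does not show whether their mRNAs were edited. The transcription factor MYC had 1 exonic site with 1 of 15 reads (6.67%, 0.169% to 31.9%). The insulin receptor substrate IRS1 had 3 exonic sites with 1 edited read each, out of 17, 14 and 7 reads.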

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

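Of 157 values under other settings, 81 kept their direction and call or stayed within the bounds set for them. Of the rest, 64 moved, 6 lost a call, 2 gained one and 4 reversed. For counts the bound was a factor of 1.5. A change from 2 to 3 lists called, or from 1839 to 1372 genes with a site, was thus counted as kept. Of the 81, 40 could not have changed: 28 under a minimum level of 5% and 1 row per position, which remove no site, 5 list results without CBX5, which is in no list, 6 gene and list results with 1 random site per gene, and 1 count under its own filter. The settings with a minimum of 2 edited reads, 1 random site per gene and other lists without ribosomal proteins were chosen after seeing the data. Minimum coverages, and minimum levels of 10% and 20%, leave fewer sites by construction; for the other changes the cause was not tested. No paired analysis was possible because each group has 1 library. Not run were the alternatives on mismatch type, an authors' score, a pseudocount, comparisons between libraries and their adjustments, regions from a reference annotation, flanking bases, the HRUAR motif, and the backgrounds of lists and chromosomes. The conversion rate has no value at minimum levels of 10% and 20%, which select on the edited reads themselves, or where no sites with 1 edited read remain.

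At a coverage of at least 10 there were 2869 sites, 668 genes with 2 or more sites and a median level of 7.14%, ribosomal proteins passed the test (odds ratio 0.335), and the 3' UTR odds ratio was 3.95. At 20 or more there were 252 sites in 215 genes, 31 genes with 2 or more, a median of 5%, 60.7% in 3' UTRs, 5.56% with a neighbour, 25 list members and 50 sites with 2 or more edited reads; 1 list was called, nuclear transport had an odds ratio of 2.03, and the rate, fitted on the sites with exactly 20 reads, was 0.303%. At 30 or more there were 22 sites, all with 2 or more edited reads, in 21 genes, 1 of them with 2 or more sites, with a median of 5.72%, 86.4% in 3' UTRs, 0% with a neighbour, 4 list members and 0 lists called; the odds ratio was 7.75 for nuclear transport, no longer called, and reversed to 0 for oncogenes. At 50 or more only 3 sites in 3 genes were left, 3 of them with 2 or more edited reads and 0 genes with 2 or more sites, with a median of 6.35%, 100% in 3' UTRs, 0% with a neighbour, 2 list members and 0 lists called, and the odds ratios of nuclear transport and of oncogenes were both 0. These reversals rest on 4 and 2 list members.

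At a level of at least 10% there were 1918 sites in 1191 genes, 474 genes with 2 or more, a median of 14.3%, 9.59% with a neighbour, 76 list members and 52 sites with 2 or more edited reads. At 20% or more there were 337 sites in 299 genes, 33 genes with 2 or more, a median of 20%, 5.34% with a neighbour, 18 list members, 14 sites with 2 or more edited reads and 1 list called; the odds ratio of oncogenes was 3.18, no longer called, and that of the 3' UTR reversed to 0.775. With at least 2 edited reads there were 93 sites in 79 genes, 10 genes with 2 or more, a median of 10.5%, 80.6% in 3' UTRs, 6.45% with a neighbour, 11 list members and 0 lists called, with odds ratios of 2.3 for nuclear transport and 3.48 for oncogenes.

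With 1 random site per gene there were 1839 sites, 50.7% in 3' UTRs, 32 with 2 or more edited reads, 0 genes with 2 or more sites and 0% with a neighbour, and the 3' UTR odds ratio of 1.95 no longer passed the test. Counted by gene, 63% had a 3' UTR site. A neighbour was found for 13%, 26.1% and 38.7% of sites within 50, 200 and 500 bases. With at least 2 sites per gene there were 79 list members, and ribosomal proteins passed the test (odds ratio 0.156).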

Other observations

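All tests in this part were chosen after the table was seen. Several genes held more than 1 site with 2 or more edited reads. ASPH had 4 such sites among 10, all in the 3' UTR. PRKAR1A, a regulatory subunit of protein kinase A, had 3 among 7 in the 3' UTR, and SON, a splicing cofactor, had 3 among 4, all exonic. CPD, TMED5, MSN, ATP13A3, EIF4EBP2, CHMP3 and ACP1 had 2 each. Beyond the sites already described, 3 edited reads were seen in HNRNPC (3 of 19), B2M (3 of 9) and CALCOCO1 (3 of 5, exonic), which were chosen for their values.

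Gene symbol families differed in how often they carried a site. Of 20056 protein-coding symbols 9.16% had one. Zinc finger genes named ZNF had sites in 20 of 517 (odds ratio 0.392, Fisher's exact adjusted p = 3.22e-05) and solute carriers in 51 of 386 (odds ratio 1.52, adjusted p = 0.0369). Olfactory receptors, genes of the nasal epithelium, had 0 of 392. The other 12 of 15 families did not pass the test, among them 13 of 77 USP and 5 of 74 RAB genes. The background includes genes not expressed in these cells, so expression was not separated from binding.

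Sites of a gene also lay close together. There were 51 pairs at 1 to 3 bases, 16 of them at adjacent positions, and 61 pairs at 4 to 10 bases. Pairs per base were 1.95 times as dense at the shorter distance (1.33 to 2.84, resampled by gene). Whether both sites of a close pair rest on the same read is not known, and the spacing of C bases was not used. The ratio therefore does not show that independent edits cluster.

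Almost all sites rested on 1 edited read: if every listed site had been edited in at least 5% of its molecules, 1108 of the 4415 sites with a coverage of at most 20 would be expected to show 2 or more edited reads, and 47 did (lowest of 10000 simulations 989). A low rate per read, fitted at 0.215% (0.162% to 0.278%), stays open: fitted at a coverage of 5 to 12 alone, it predicted 31.8 sites with 2 or more edited reads at 13 to 20 (19.9 to 47.7), and 29 were seen. Fitted by region, the rate was 0.282% (0.202% to 0.380%) in 3' UTRs, 0.136% (0.0751% to 0.224%) at exonic sites and 0.0853% (0.00488% to 0.374%) in 5' UTRs. Whether all sites share 1 rate was not settled: 4 sites had 3 or more edited reads against 0.730 expected at the upper bound of the rate (exact Poisson p = 0.00665), but copies of 1 edited molecule could give the same excess, and the treatment of duplicate reads is not known. A low rate may come from sparse editing or from errors of reverse transcription, sequencing or alignment. The table cannot separate these because it lists the other libraries at 0. No biological explanation was tested.

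The 3' UTR share was higher at sites with 2 or more edited reads. At a coverage of at most 20, unequal coverage between regions did not account for all of it. With edited reads permuted within each coverage, 26.3 3' UTR sites were expected and 34 were seen (permutation p = 0.0252). This test treats sites as independent. Over all coverages the odds ratio was 3.30, against 2.07 at a coverage of at most 20, so a part played by coverage remains. Above 20 no site with 1 edited read is listed, and no such test is possible. A few genes with several such sites did not account for it by resampling. The 47 sites lay in 43 genes, and the odds ratio resampled by gene had a lower bound of 1.09. Both margins are narrow. With 1 random site per gene the odds ratio of 1.95 did not pass the test, so a part played by such genes is not excluded. At a coverage of at least 10 the odds ratio was 3.95, so sites with fewer reads lowered it. Differences in base composition, mapping, duplicate reads or error between regions stay open, as does editing by the fusion itself, and no biological explanation was tested.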
